A study of Rattus norvegicus with 28 samples.

How the data were processed

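Gene expression was measured in the terminal ileum of newborn rat pups with an Affymetrix rat array, 1 array per pup. Per the labels, total RNA was hybridised from 28 separate pups in 9 groups. Breast-fed pups were killed on day 1, 2, 3 or 4 of life (3 arrays per day). Pups given formula and hypoxic stress 3 times a day were killed on the same days (3 arrays per day). Unfed newborns made up the last group (4 arrays, treated as day 0). Formula and hypoxia were always given together, so their effects could not be separated. Replicate numbers and groups were taken from the titles and descriptions. The samples were registered in a pair of separate accession runs of 19 and 9 arrays, which were treated as a possible batch of array processing. The second run held breast-fed day 1 replicate 2, breast-fed day 3 replicate 3, all 3 breast-fed day 4 arrays, formula and hypoxia day 4 replicate 3, and unfed replicates 2 to 4.

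The deposited values were probe set intensities on a linear scale, 1 value per probe set and array, ranging from 0.000562 to 22483 with a median of 37.6. From the values, 26 of the 28 arrays had a 2% trimmed mean between 150.2 and 150.5, so the authors had scaled them to a common target. The trimmed mean of breast-fed day 1 replicate 2 was 109.2 and that of breast-fed day 4 replicate 1 was 209.2. The software, background correction and summary method behind the intensities are not given in the sources used here. Median deposited signals were 38.5, 28.7 and 32.7 for breast-fed replicates 1 to 3 on day 1, 41.7, 46.0 and 38.1 on day 2, 38.0, 30.3 and 32.6 on day 3, and 53.9, 34.9 and 37.9 on day 4. Under formula and hypoxia they were 34.6, 33.0 and 40.4 on day 1, 43.4, 40.2 and 40.8 on day 2, 48.1, 39.0 and 37.9 on day 3, and 46.5, 40.3 and 38.3 on day 4. The unfed replicates 1 to 4 had medians of 32.0, 42.6, 29.8 and 25.8. These medians fit a linear scale with scaling of the trimmed mean and no centring of the median. Whether the scaling of the 2 deviating arrays was left out or was done to another target stays unknown.

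The array carried 8799 probe sets, of which 59 were controls and were left out of the tests. The platform annotation gave 1 gene symbol for 7006 of the other 8740 probe sets, several symbols for 308 and none for 1426. Of the probe sets with 1 symbol, 6985 matched a current RefSeq gene and 0 symbols were updated. Because the trimmed means were unequal, the intensities were quantile normalised between arrays, a pseudocount of 8 was added, and the values were converted to log2. Probe sets were kept when their mean log2 value over the 28 arrays was above the 40th percentile of the non-control probe sets, which corresponds to a signal of 24.0. This left 5244 probe sets. The probe set with the highest mean was then used for each gene, which gave 3185 genes tested of 4736 genes with a symbol.

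Differences were estimated with limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted to all 28 arrays (19 residual degrees of freedom), followed by empirical Bayes moderation with an intensity trend and Benjamini-Hochberg adjustment over the genes tested. Genes with an adjusted p under 0.05 were called, all tests were two-sided, and confidence intervals are 95% intervals from the same model. The comparisons were formula and hypoxia against breast feeding as an equally weighted mean over days 1 to 4 and on each day, the change of that effect from day 1 to day 4, an F test of any difference between the 4 daily effects, day 1 of each regimen against unfed newborns, and day 4 against day 1 within each regimen. The correlation across genes between the mean of the day 2 and day 3 effects and the breast-fed change from day 1 to day 4, which share no array, was tested by exact permutation of the regimen labels within days (400 arrangements).

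For each comparison with a direction, 32 gene lists covering pathways and cell types were tested with limma's camera, with a preset correlation between genes of 0.01 and adjustment over the 32 lists. Camera with a correlation estimated for each list was run beside it, as was limma's fry, which tests whether the genes of a list move on balance in one direction without setting them against other genes. The lists covered the hypoxia response, inflammatory cytokines and NF-kB targets, antimicrobial and acute phase proteins, brush border digestion and uptake, fat absorption, fatty acid oxidation, cholesterol synthesis, bile acid handling, arginine and polyamine metabolism, apoptosis, antioxidant and xenobiotic enzymes, metallothioneins and iron handling, heat shock and endoplasmic reticulum stress, immediate early genes, cell proliferation, glucocorticoid and ion transport genes, oxidative phosphorylation, junctions, and interferon response and antigen presentation. Cell type lists covered goblet and Paneth cells, enteroendocrine cells, smooth muscle, neurons and glia, macrophages and granulocytes, lymphocytes, mast cells, red cells, exocrine pancreas, fat tissue, liver, fibroblasts and matrix, and endothelium.

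The groups, lists, comparisons, tests, most alternatives and the rule for naming genes were set before the data were examined. For the mean over days, the 12 largest rises and 12 largest falls were named among called genes whose daily difference had the same sign on all 4 days. For the other comparisons with a direction, the 5 largest rises and 5 largest falls among called genes were named, and for the F test the 5 genes with the smallest p among those called. Up to 4 members of each list with the smallest p were eligible for naming, and 17 genes of interest in this disease were fixed whatever their values. Only genes read by a probe set with a single symbol were named, and genes named outside the rule are described as chosen after their values were seen.

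Alternatives covered the deposited scaling and a common median in place of quantile normalisation, pseudocounts of 2 and 32, no filter and a filter at the 60th percentile, 1 test per probe set, moderation without a trend, a fit of only the groups compared, array weights, the replicate number as a block, the accession run as a term, each accession run alone, and each array left out in turn. A pair of alternatives was added after the data were seen. In 1 of them both arrays that had lost abundant probe sets were left out, and in the other the 3′ to 5′ signal ratio of the beta-actin controls was a term. The analysis was tested on simulated data drawn from the real genes. For the mean over days, 87% of 100 genes changed 2-fold and 98% of 100 genes changed 4-fold were recovered, with 11 unchanged genes called. On single days, 34% to 40% of genes changed 2-fold and 86% to 91% of genes changed 4-fold were recovered. For lists, 5 of 5 lists shifted by 0.5 log2 and 0 of 15 unshifted lists were called. The simulated genes varied independently, so this test does not cover lists whose members vary together. When the real regimen labels were split within days, the median number of lists called was 2 and the highest 8. Figures and summary tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.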

Results

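Transcript levels were compared in the terminal ileum of rat pups reared in a model of necrotizing enterocolitis, an inflammatory disease of the immature bowel, in which pups receive formula in place of breast milk together with repeated hypoxia. The arrays came from 12 breast-fed pups, 12 pups given formula and hypoxia and 4 unfed newborns. Each regimen had 3 pups on each of days 1 to 4. A pair of breast-fed arrays stood apart. Breast-fed day 3 replicate 3 had lost 69 of 754 abundant probe sets (median signal over the other arrays above 500, own signal more than 16-fold lower), and breast-fed day 4 replicate 2 had lost 48 of 757. In the other 26 arrays 0 to 2 were lost. The median correlation of these 2 arrays with the others was 0.809 and 0.821, against 0.867 to 0.935 for the rest. The 3′ to 5′ ratio of the beta-actin controls, a sign of RNA integrity, was highest in formula and hypoxia day 1 replicate 2 at 4.17. Between the regimens, the GAPDH ratio (exact permutation p = 0.516), the actin ratio (p = 0.946), the median signal (p = 0.189) and the median correlation (p = 0.898) did not differ beyond chance within days. With 3 arrays per group, the number of pups limited the precision on single days.

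The first question was how the ileum under formula and hypoxia differed from that of breast-fed pups of the same age. Among the genes named, transcripts of 3 chymases fell furthest. Averaged over days 1 to 4, Mcpt4, a mast cell chymase, was 8.44-fold lower (95% confidence interval 6.05 to 11.8, n = 12 against 12 arrays), with a mean signal of 7.22 ± 9.10 (SD) against 130 ± 82.9 in breast-fed pups. The lower signal lies below the pseudocount of 8, so this fold is set by it, and the log2 change went from -3.90 to -1.90 between pseudocounts of 2 and 32. Vch, vascular chymase, was 8.51-fold lower (5.89 to 12.3) and Mcpt1, another mast cell chymase, was 5.12-fold lower (3.60 to 7.29). The largest rises were those of Cyp3a9, a cytochrome P450 enzyme, which was 4.72-fold higher (3.19 to 6.99), and Lgals3, which encodes galectin-3 and was 4.72-fold higher (3.50 to 6.36). In all, 364 of 3185 genes passed the limma test, 149 higher and 215 lower, and 64 of them changed more than 2-fold. With arrays scaled to a common median the split was 90 higher and 245 lower. The median standard error was 0.16 on the log2 scale.

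**Figure D1:**
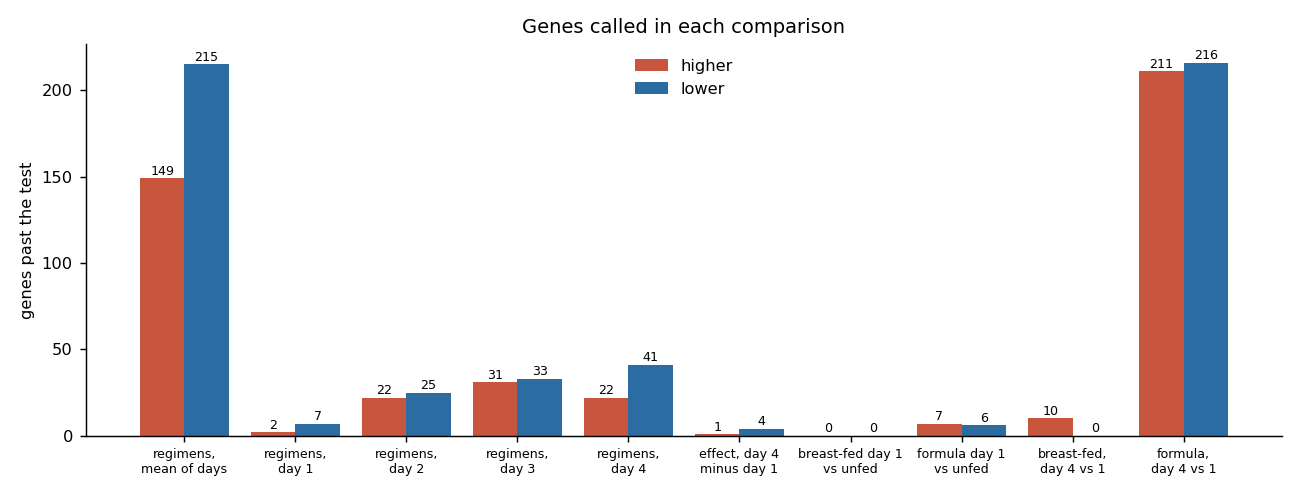
Number of genes past the limma test (vertical axis, genes) that were higher and lower in each comparison with a direction. The mean over days 1 to 4 gave 149 higher and 215 lower genes, and formula and hypoxia day 4 against day 1 gave 211 and 216.

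**Figure D2:**
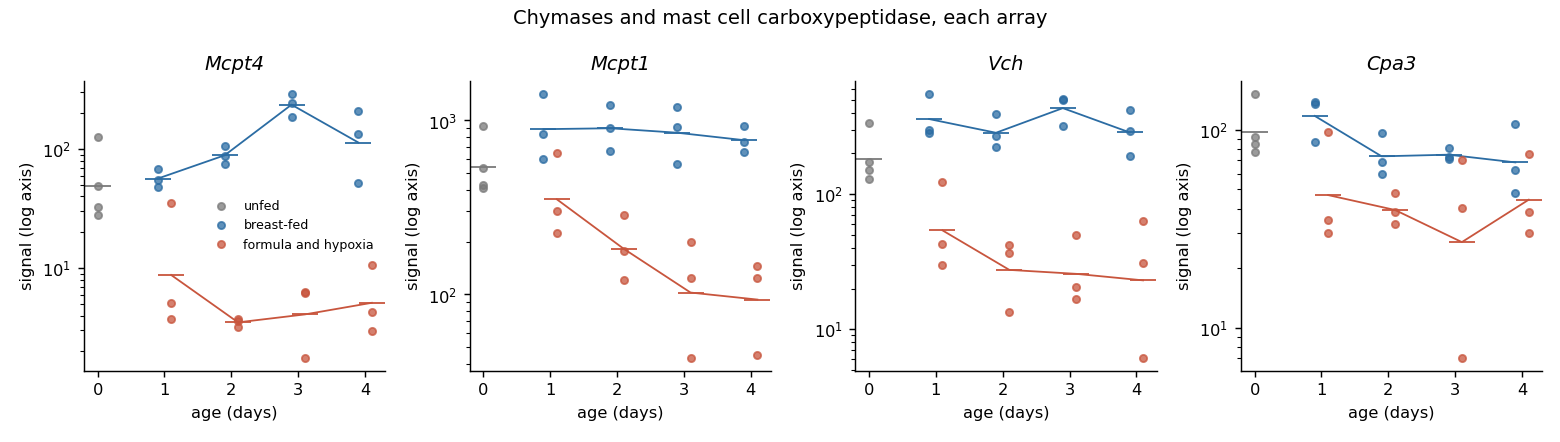
Quantile normalised signal (log axis) of Mcpt4, Mcpt1, Vch and Cpa3 against age in days, 1 point per array, in unfed, breast-fed and formula and hypoxia pups. Horizontal marks joined by lines are geometric means of the groups, and mean signals over days 1 to 4 were 130 against 7.22 for Mcpt4 in breast-fed against formula and hypoxia pups.

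Other large rises included Cyp27a1, the sterol 27-hydroxylase, at 3.76-fold (2.86 to 4.93), and Muc3, a membrane mucin, at 3.56-fold (2.60 to 4.89). Areg, a ligand of the epidermal growth factor receptor, was 2.99-fold higher (2.16 to 4.13), as was the alanine aminotransferase gene Gpt at 2.99-fold (2.12 to 4.22). Klf9, a Krüppel-like transcription factor, rose 2.53-fold (1.78 to 3.60), Ptprr, a tyrosine phosphatase, 2.64-fold (2.08 to 3.36) and LOC102549726 2.71-fold (2.17 to 3.38). Ly6al rose 2.72-fold (1.59 to 4.64), and the glutathione transferases Gsta3 and Gstp1 rose 2.55-fold (1.49 to 4.38) and 2.52-fold (1.57 to 4.04). Ccl11, the eosinophil chemoattractant eotaxin, was 4.87-fold lower (3.39 to 7.02), and Dio1, the type 1 deiodinase that activates thyroid hormone, was 4.55-fold lower (3.33 to 6.23). Fam111a was 3.75-fold lower (1.85 to 7.59) and Serpinb9, an inhibitor of granzyme B, 3.70-fold lower (2.75 to 4.98). Tcf21, a transcription factor of mesenchymal cells, was 3.09-fold lower (2.20 to 4.33), the fetal serum protein gene Afp 2.93-fold lower (1.84 to 4.66), and the matrix genes Lum, Spp1 and Postn 2.91-fold (2.12 to 4.00), 2.78-fold (2.05 to 3.77) and 2.71-fold (1.85 to 3.99) lower.

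Adjusted p-values of these 24 genes ran from 3.44e-09 for Mcpt4 to 0.0203 for Gsta3. In 18 of the 24 genes all 12 formula and hypoxia arrays lay on the same side of the breast-fed mean of their day, and Gstp1 had the fewest, 10 of 12. For Muc3 the other probe sets gave 0.81 and 0.75 on the log2 scale in place of 1.83, for Gsta3 0.24 and 0.38 in place of 1.35, and for Tcf21 -0.44 in place of -1.63. Some folds moved with the pseudocount. Between pseudocounts of 2 and 32 the change of Vch went from -3.35 to -2.47, that of Ccl11 from -2.91 to -1.39 and that of Serpinb9 from -2.32 to -1.14. Within accession run 1, which covers days 1 to 3, 163 genes passed, and within run 2, day 4 with a single formula array, limma called 0 genes (0 of the 24). Gsta3 (log2 0.70, adjusted p = 0.0534), Gstp1 (0.69, 0.0527), Ly6al (0.53, 0.430) and Afp (-1.01, 0.157) did not pass within run 1, and the first 3 also missed it with the run as a term, at adjusted p = 0.125, 0.0841 and 0.0589. Over all alternatives the adjusted p of Gsta3 ran from 0.00629 to 0.125, of Gstp1 from 8.41e-05 to 0.0841, of Ly6al from 0.00261 to 0.430 and of Afp from 0.000371 to 0.157, run 2 alone apart.

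Of the 32 gene lists, 7 were called for the mean over days, 3 higher and 4 lower. Immediate early genes, the first transcripts to respond to a stimulus, rose together. Of 23 measured, 9 rose and 14 did not pass, with 15 higher when adjusted over the list alone, a median change of 0.54 and camera adjusted p = 4.54e-08 (adjusted p = 0.0118 with an estimated correlation). Fos rose by 1.03, Junb by 0.97 and Zfp36 by 0.75. The list mean was higher than that of breast-fed pups of the day in 12 of 12 formula and hypoxia arrays. Cell proliferation genes fell, with 7 of 25 lower and 0 higher (9 lower adjusted over the list alone), a median of -0.22 and adjusted p = 0.00189 (adjusted p = 0.0269 with an estimated correlation), in 10 of 12 arrays. Mcm6, a replication helicase subunit, changed by -0.79, Stmn1 by -0.76 and the mitotic checkpoint kinase gene Bub1b by -0.71. Within accession run 1 both lists were called, at adjusted p = 8.66e-06 and 4.6e-06. Within run 2 the immediate early list had adjusted p = 0.000163, and the proliferation list lost its call (0.727).

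The other 5 called lists lost their call with an estimated correlation. Red cell markers were higher in 5 of 9 genes (5 adjusted over the list alone, median 0.38, adjusted p = 0.00315, 12 of 12 arrays), with adjusted p = 0.101 with an estimated correlation. Among them the beta globin gene Hbb-b1 rose by 0.51 and Alas2, which encodes the first enzyme of heme synthesis in red cells, by 0.69. Within run 2 the sign of both turned, to -0.0350 and -0.133. Interferon response and antigen presentation genes were lower in 4 of 18 (4 adjusted over the list alone, median -0.20, adjusted p = 0.031, 11 of 12 arrays), with adjusted p = 0.174 with an estimated correlation. The MHC light chain gene B2m changed by -0.44 and the transcription factor gene Irf1 by -0.75. These calls were lost within run 1 at adjusted p = 0.153 and 0.138 (ranges over alternatives 0.0014 to 0.153 and 0.00356 to 0.138, run 2 alone apart). Without breast-fed day 1 replicate 3 the adjusted p of this list was 0.0522. Within run 1 the red cell list had adjusted p = 0.000866 and the interferon list 0.00848, and within run 2 both lost their call (0.720 and 0.324).

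Fibroblast and matrix genes were lower in 7 of 32 and higher in 1, with the same counts adjusted over the list alone (median -0.14, adjusted p = 0.031, 10 of 12 arrays; adjusted p = 0.459 with an estimated correlation). Besides Lum, Spp1 and Postn, the matrix metalloproteinase gene Mmp10 changed by -1.31 and Serpinh1, a collagen chaperone gene, by -0.89. This list lost its call without breast-fed day 2 replicate 2 (0.0893), formula and hypoxia day 1 replicate 1 (0.0522), day 3 replicate 3 (0.0569) or day 4 replicate 3 (0.0576). Antioxidant and xenobiotic enzymes were higher in 7 of 31 and lower in 2 (8 and 3 adjusted over the list alone; median 0.33, adjusted p = 0.032, 11 of 12 arrays; adjusted p = 0.4 with an estimated correlation). Besides Cyp3a9 and both glutathione transferases, Gclm, a subunit of the enzyme that limits glutathione synthesis, rose by 0.63 and xanthine dehydrogenase, Xdh, changed by -1.03. The call ended without breast-fed day 1 replicate 3 (0.0580), day 2 replicate 2 (0.0698), day 3 replicate 3 (0.0648) or day 4 replicate 2 (0.115). It also ended without formula and hypoxia day 1 replicate 2 (0.0518), day 3 replicate 3 (0.0569) or day 4 replicate 3 (0.0576), and without both arrays that had lost probe sets it was 0.225. With the deposited scaling, array weights or the run as a term it was 0.0695, 0.0596 or 0.0647. Within run 1 the fibroblast list had adjusted p = 0.0487 and the antioxidant list 0.248, and within run 2 they had 0.000453 and 0.00137.

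Of 8 mast cell markers, 4 were lower (4 lower and 1 higher adjusted over the list alone), with a median of -0.24, a mean of -0.74 and adjusted p = 0.032 (adjusted p = 0.4 with an estimated correlation), in 12 of 12 arrays. Mcpt4 and Mcpt1 were joined by Cpa3, mast cell carboxypeptidase, at -0.90 and by Cma1, another chymase, at -0.46 (adjusted p = 0.0457, reaching 0.0936 when single arrays were left out). The tryptase genes Tpsab1 and Tpsb2 had values of 0.22 and 0.30, Mcpt1l1 0.40 and Hpgds -0.02, and these did not pass over all genes. Mcpt1, Mcpt4, Vch and Cma1 belong to 1 family of related chymases, and cross-hybridisation among their probe sets was not tested. The call of the list was lost with the 60th percentile filter (0.158) and without breast-fed day 1 replicate 3 (0.0522), day 2 replicate 2 (0.0666), day 3 replicate 2 (0.0575) or formula and hypoxia day 4 replicate 3 (0.0576). It was 0.303 within run 1 and 0.00948 within run 2. The number of called lists was 4 without breast-fed day 1 replicate 3, breast-fed day 2 replicate 2 or formula and hypoxia day 4 replicate 3, and 6 within each accession run. Each value within run 2 rests on 1 formula and hypoxia pup, day 4 replicate 3, whose spread was taken from the other groups, so these values are no independent repeat. Lists called in run 2 and not in run 1 included cholesterol synthesis and fat tissue markers (each higher, adjusted p = 0.000786).

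**Figure D3:**
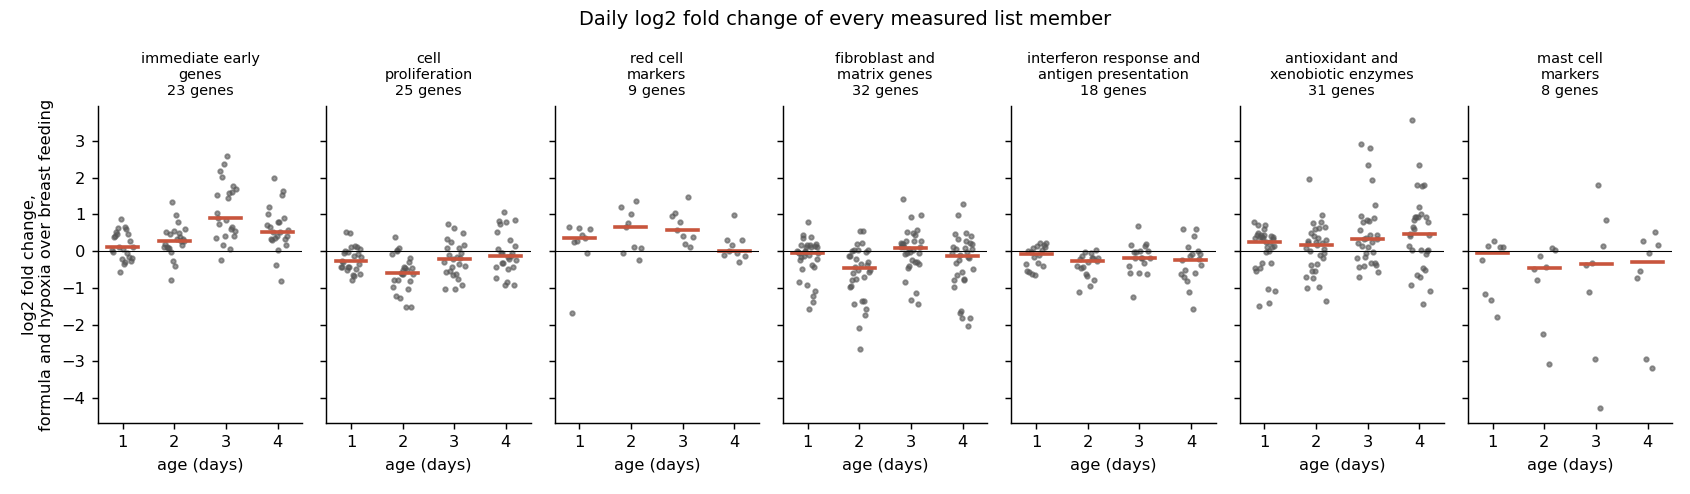
Change on each day (log2, formula and hypoxia minus breast-fed) of every measured member of the 7 called gene lists, 1 point per gene, with the median as a bar. Over the mean of days, the median was 0.54 for the 23 immediate early genes and -0.22 for the 25 proliferation genes.

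The remaining 25 lists did not pass with all arrays. Inflammatory cytokines and NF-kB targets had 5 of 23 higher and 1 lower (the same adjusted over the list alone; median 0.22, adjusted p = 0.0719), among them the NF-kB inhibitor gene Nfkbia at 1.19 and the TNF receptor gene Tnfrsf1a at 1.14. It was called with a common median (0.0418), with 1 test per probe set (0.0169) and without formula and hypoxia day 2 replicate 3 (0.0409) or breast-fed day 4 replicate 3 (0.0488). Junction genes had 1 of 9 higher (1 over the list alone; median 0.27, adjusted p = 0.0624), the claudin gene Cldn3 at 1.15. This list was called with 1 test per probe set (0.00816) and without any of 10 single arrays. These were breast-fed day 1 replicate 1 (0.0174), day 2 replicate 3 (0.0483), day 3 replicate 1 (0.0444) and day 4 replicates 1 (0.0499) and 3 (0.0462), and formula and hypoxia day 1 replicate 2 (0.0313), day 2 replicates 2 (0.0341) and 3 (0.0462), day 3 replicate 2 (0.0441) and day 4 replicate 2 (0.0478). Bile acid handling had 1 of 8 higher (5 over the list alone; median 0.35, adjusted p = 0.0719), and was called without breast-fed day 2 replicate 1 (0.0429) or formula and hypoxia day 3 replicate 1 (0.0369). Exocrine pancreas markers had 1 of 8 higher (3 over the list alone; median 0.26, adjusted p = 0.187), and glucocorticoid and ion transport genes 3 of 18 higher (3 over the list alone; median 0.02, adjusted p = 0.354), the water channel gene Aqp8 at 0.70, the sodium-proton exchanger gene Slc9a3 at 1.06 and the kinase gene Sgk1 at 0.86. Antimicrobial and acute phase proteins had 1 of 12 higher and 1 lower (median 0.11, adjusted p = 0.378), lipocalin 2, Lcn2, at 1.29 and the ribonuclease gene Rnase4 at -0.73. The latter was -0.25 within run 1 (adjusted p = 0.477, 0.000447 to 0.477 over alternatives, run 2 alone apart). Brush border genes had 2 of 16 higher and 1 lower (2 and 3 over the list alone; median -0.22, adjusted p = 0.455), with the fructose transporter gene Slc2a5 at 1.25. Fat absorption genes had 2 of 16 higher and 1 lower (4 and 1 over the list alone; median 0.16, adjusted p = 0.46). Arginine and polyamine metabolism had 3 of 18 higher and 3 lower (4 and 5 over the list alone; median -0.00, mean 0.05, adjusted p = 0.879), with ornithine aminotransferase, Oat, at -0.79.

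Heat shock and endoplasmic reticulum stress genes had 1 of 21 higher and 2 lower (median -0.17, adjusted p = 0.509), among them the chaperone gene Hspa5 at -0.95. This list was called with 1 test per probe set (0.0161), without breast-fed day 3 replicate 3 (0.0335), without both arrays that had lost probe sets (0.00404) and within run 1 (0.000589). Goblet and Paneth cell markers had 1 of 8 higher and 2 lower (median 0.12, adjusted p = 0.879). Muc3 rose, and the secreted goblet cell genes Muc2 and Tff3 had changes of -1.08 and -0.69. Other probe sets for Muc2 gave -0.10 and 0.03. Macrophage and granulocyte markers had 2 of 14 higher and 4 lower (3 and 4 over the list alone; median 0.13, adjusted p = 0.879), with Lgals3 higher and the protease gene Ctss at -0.82, Coro1a at -1.13 and Cd53 at -0.96. Lymphocyte markers had 1 of 11 lower (median -0.11, adjusted p = 0.5), liver secreted proteins 2 of 12 lower (median 0.08, mean -0.12, adjusted p = 0.858), smooth muscle 1 of 16 lower (median -0.05, adjusted p = 0.549) and fat tissue 1 of 11 higher (median 0.12, adjusted p = 0.553). Enteroendocrine cells (13 genes; median 0.05, mean -0.04, adjusted p = 0.879), neurons and glia (23 genes; median 0.10, adjusted p = 0.73) and endothelium (7 genes; median 0.19, adjusted p = 0.635) had 0 called members. Camera placed the liver, enteroendocrine and arginine lists on the lower side.

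For the hypoxia response, 1 of 19 genes was lower, the collagen hydroxylase gene P4ha1 at -0.56, and 0 were higher (median 0.08, adjusted p = 0.635). Cholesterol synthesis had 1 of 16 higher (median 0.04, adjusted p = 0.73), Insig1, a sterol sensor gene, at 1.29. Fatty acid oxidation had 2 of 28 higher and 1 lower (median 0.01, adjusted p = 0.853), with the carnitine palmitoyltransferase gene Cpt1a at 0.77. Apoptosis genes had 1 of 13 higher and 1 lower, the caspase gene Casp1 at -1.39 (median -0.11, adjusted p = 0.754). Oxidative phosphorylation (30 genes; median 0.09) and metallothioneins and iron handling (8 genes; median -0.01) had 0 called members, each with adjusted p = 0.879. Where 1 set of counts is given for a list, adjustment over the list alone gave the same counts. The call of P4ha1 was lost with the deposited scaling (0.0601), with the run as a term (0.0983) and within run 1 (0.112). Its range was 0.00415 to 0.112, run 2 alone apart. Over all lists fry called 11, and camera with an estimated correlation called 2.

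Among genes fixed in advance for their part in this disease, Hbb rose by 0.37 (adjusted p = 0.00593). Its call ended when arrays were scaled to a common median (0.166, range 0.00328 to 0.166, run 2 alone apart). Within run 2 the sign of Hbb turned, to -0.0577. The inflammatory genes Il1b (-0.31, adjusted p = 0.158) and Nos2 (-0.73, 0.190), lactase, Lct (-0.19, 0.438), the bile acid transporter gene Slc10a2 (0.05, 0.900) and Vegfa (-0.17, 0.598) did not pass. Nor did heme oxygenase 1, Hmox1 (0.78, 0.0963), carbamoyl phosphate synthetase 1, Cps1 (-0.47, 0.0930), or the ileal bile acid binding protein gene Fabp6 (0.44, 0.101), for which another probe set gave -1.55. Tnf, Il6, Ptgs2 and Pla2g2a were below the filter, and Cxcl1 had no probe set with a single symbol.

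On day 1 the regimens differed in few genes. Muc3 was 4.91-fold higher (95% confidence interval 2.61 to 9.24, n = 3 against 3 arrays) and Efna1, an ephrin ligand gene, 2.44-fold higher (1.66 to 3.59). Vch was 5.84-fold lower (2.80 to 12.2), Serpinb9 3.69-fold (2.04 to 6.68), Mmp10 3.00-fold (1.94 to 4.64), Cbx5, a heterochromatin protein gene, 2.84-fold (1.80 to 4.50) and Arsb, a lysosomal sulfatase gene, 2.64-fold (1.77 to 3.92). Adjusted p-values of these 7 genes lay between 0.0348 and 0.0462. For each, all 3 formula and hypoxia arrays lay beyond all 3 breast-fed arrays of the day. Chance gives such a separation in 10% of genes. Named genes were chosen for large differences between the same arrays, so a lack of overlap is no added support in this or any later comparison. Between pseudocounts of 2 and 32 the log2 change of Cbx5 went from -2.17 to -0.72 and that of Serpinb9 from -2.25 to -1.22, and the calls of Cbx5 with 32 and of Serpinb9 with 2 were lost. In all, 9 genes passed, 2 higher and 7 lower. Brush border genes (16, median -0.47, adjusted p = 0.0199) and smooth muscle markers (16, median -0.40, adjusted p = 0.0196) were lower as lists with 0 members called (1 brush border gene lower adjusted over the list alone), at adjusted p = 0.549 and 0.303 with an estimated correlation. The count was 0 with the run as a term, and 0 without breast-fed replicate 1 or formula and hypoxia replicate 1 or 3 (limma, 291 genes at an unadjusted p under 0.05 with all arrays). Without breast-fed replicate 2 or 3 it was 1, without formula and hypoxia replicate 2 it was 3, and within run 1 it was 6.

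On day 2, Lgals3 was 8.54-fold higher (4.69 to 15.5, n = 3 against 3), Slc2a5 5.15-fold (2.80 to 9.45), Cyp27a1 4.36-fold (2.54 to 7.51), Muc3 4.34-fold (2.30 to 8.16) and Acsl4, a long-chain acyl-CoA synthetase gene, 3.66-fold (1.87 to 7.16). Mcpt4 was 8.40-fold lower (4.32 to 16.4), Vch 8.07-fold (3.87 to 16.8), Ccl11 6.50-fold (3.13 to 13.5), Mmp10 6.39-fold (4.13 to 9.88) and Muc2 6.15-fold (3.03 to 12.5). In all, 47 genes passed, 22 higher and 25 lower, and the adjusted p-values of the named genes ran from 1.46e-05 for Mmp10 to 0.0444 for Acsl4. The change of Mcpt4, whose signal under formula and hypoxia was below the pseudocount, went from -4.04 to -1.77 between pseudocounts of 2 and 32, that of Ccl11 from -3.43 to -1.64, that of Vch from -3.27 to -2.37 and that of Mmp10 from -2.93 to -2.04. For each of the 10 named genes the 3 arrays of either regimen did not overlap. Cell proliferation genes were lower (1 of 25 over all genes, 4 over the list alone; median -0.60, adjusted p = 2.89e-07, and adjusted p = 0.000906 with an estimated correlation). Fibroblast and matrix genes (3 of 32 lower, 5 over the list alone; median -0.46, adjusted p = 1.93e-06) and mast cell markers (2 of 8 lower, 2 over the list alone; median -0.46, adjusted p = 0.00209) were also lower, at adjusted p = 0.0860 and 0.149 with an estimated correlation. So were interferon and antigen presentation genes (0 of 18, median -0.28, adjusted p = 0.006), heat shock genes (1 of 21, median -0.55, adjusted p = 0.0142) and smooth muscle markers (0 of 16, median -0.39, adjusted p = 0.0334), at adjusted p = 0.0860, 0.310 and 0.310 with an estimated correlation. Red cell markers (1 of 9, 4 over the list alone; median 0.65, adjusted p = 0.0011), fat absorption genes (1 of 16, 3 over the list alone; median 0.33, adjusted p = 0.00886) and immediate early genes (0 of 23, 2 over the list alone; median 0.27, adjusted p = 0.0142) were higher, at adjusted p = 0.0860, 0.249 and 0.249 with an estimated correlation. The count fell with any single array left out, to 24, 19 or 28 without breast-fed replicate 1, 2 or 3 and to 22, 25 or 24 without formula and hypoxia replicate 1, 2 or 3, and the calls of Acsl4 (highest adjusted p = 0.235) and Muc3 (0.0646) were lost in some of these. It was 43 within run 1.

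On day 3, Mcpt4 was 19.5-fold lower (10 to 37.9, n = 3 against 3), Vch 12.9-fold (6.17 to 26.8), Mcpt1 7.65-fold (3.77 to 15.5), Tcf21 7.61-fold (3.86 to 15) and Dio1 7.23-fold (3.87 to 13.5). Pck1, the gluconeogenic enzyme phosphoenolpyruvate carboxykinase, was 10.1-fold higher (2.91 to 34.9), Cyp3a9 7.54-fold (3.44 to 16.5), Gstp1 7.06-fold (2.75 to 18.1), Cyp27a1 6.40-fold (3.72 to 11) and the transcription factor gene Jun 6.01-fold (2.55 to 14.2). In all, 64 genes passed, 31 higher and 33 lower, and adjusted p-values of the named genes ran from 6.14e-06 for Mcpt4 to 0.0427 for Pck1, with no overlap between the arrays of the regimens in any of the 10. The fold of Mcpt4 depends on the pseudocount, and its log2 change went from -5.23 with 2 to -2.87 with 32. With the same pseudocounts Vch had -3.97 and -2.98, Tcf21 -3.26 and -2.16, Dio1 -3.13 and -2.23, Pck1 3.62 and 2.70, and Jun 3.06 and 1.90. Immediate early genes were higher (7 of 23, 12 over the list alone; median 0.92, adjusted p = 1.28e-12, and adjusted p = 0.00103 with an estimated correlation). Junction genes (1 of 9, 1 over the list alone; median 0.72, adjusted p = 0.0015), red cell markers (1 of 9, 4 over the list alone; median 0.59, adjusted p = 0.0014) and antioxidant enzymes (2 of 31, 5 over the list alone; median 0.32, adjusted p = 0.00712) were higher, at adjusted p = 0.208, 0.0885 and 0.373 with an estimated correlation. The array with the most lost probe sets was a breast-fed array of this day. Without breast-fed replicate 3 the count was 30 and Jun and Pck1 had log2 changes of 1.58 and 2.62 (adjusted p = 0.164 and 0.249). Gstp1 had 1.34 there in place of 2.82 and was still called (0.0312), and within run 1 it had 1.41 and was not (0.0893). Without formula and hypoxia replicate 1 the count was 29 and Pck1, Gstp1 and Jun had adjusted p = 0.188, 0.0750 and 0.0667. The call of Pck1 also ended without breast-fed replicate 1 (0.0601) or formula and hypoxia replicate 3 (0.0907), that of Gstp1 without formula and hypoxia replicate 2 (0.0513) and that of Jun without replicate 3 (0.0852). Over all alternatives the adjusted p ran from 0.0041 to 0.412 for Gstp1, 0.00424 to 0.342 for Jun and 0.0255 to 0.249 for Pck1. Within run 1 the count was 30.

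On day 4, Dio1 was 9.42-fold lower (5.04 to 17.6, n = 3 against 3), Mcpt4 9.05-fold (4.65 to 17.6), Vch 8.65-fold (4.15 to 18.0), Fbp1, the gluconeogenic enzyme fructose bisphosphatase 1, 8.10-fold (4.48 to 14.6) and Mcpt1 7.59-fold (3.74 to 15.4). Ly6al was 12.4-fold higher (4.26 to 36.1), Cyp3a9 11.8-fold (5.40 to 25.9), Lgals3 5.26-fold (2.89 to 9.57), Fos 4.01-fold (2.23 to 7.20) and LOC102549726 3.96-fold (2.54 to 6.17). In all, 63 genes passed, 22 higher and 41 lower, and the named genes had adjusted p-values from 0.00022 to 0.0103, with no overlap between the arrays of the regimens. With pseudocounts of 2 and 32 the change of Mcpt4 was -3.98 and -1.99, that of Vch -3.47 and -2.38 and that of Dio1 -3.46 and -2.63. Immediate early genes (2 of 23; 7 higher and 1 lower over the list alone; median 0.52, adjusted p = 5.43e-05) and fat tissue markers (0 of 11, 2 over the list alone; median 0.66, adjusted p = 0.00603) were higher, at adjusted p = 0.0467 and 0.0451 with an estimated correlation. Inflammatory genes (1 of 23, 2 over the list alone; median 0.36) and antioxidant enzymes (2 of 31, 6 over the list alone; median 0.48) were higher with adjusted p = 0.0172 each, and adjusted p = 0.250 and 0.326 with an estimated correlation. The count was 16 without formula and hypoxia replicate 1, 29 without replicate 2 and 26 without breast-fed replicate 2, which had lost probe sets. In these the adjusted p of Fos was 0.0571, 0.0537 and 0.0595, and its log2 change without breast-fed replicate 2 was 1.25. Ly6al had 0.101 without formula and hypoxia replicate 1 and 0.0630 without breast-fed replicate 2. All 3 breast-fed arrays of this day belong to accession run 2 and only replicate 3 of the other regimen does. With the run as a term the count was 19, and within run 2 limma called 0 genes (478 at an unadjusted p under 0.05 with all arrays).

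The change of the difference between the regimens from day 1 to day 4 was tested as an interaction. Fbp1 had the largest fall of the effect, by 3.48 on the log2 scale (SE 0.59, adjusted p = 0.0116). Its mean signal in breast-fed pups was 129 on day 1 and 646 on day 4, and under formula and hypoxia 184 and 85.1. Itih3, which encodes a serum inhibitor of the inter-alpha-trypsin family, fell by 2.42 (SE 0.49, adjusted p = 0.0303), from a mean signal of 37.2 to 222 in breast-fed pups and from 41.4 to 36.6 in the others. Cd1d1, a lipid antigen-presenting molecule, fell by 1.85 (SE 0.33, adjusted p = 0.0141) and Bex3 by 1.47 (SE 0.28, adjusted p = 0.0258). Me1, malic enzyme 1, had a rise of the effect of 2.69 (SE 0.53, adjusted p = 0.0283), with signals of 120 and 70.7 in breast-fed pups and 39.2 and 213 in the others. These 5 were the only genes called, 1 rising and 4 falling. The F test over all 4 days called 3 genes, Fbp1, Cd1d1 and Mmp10, each at adjusted p = 0.0470. The daily log2 differences of Mmp10 were -1.58, -2.68, -0.25 and -0.75.

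**Figure D4:**
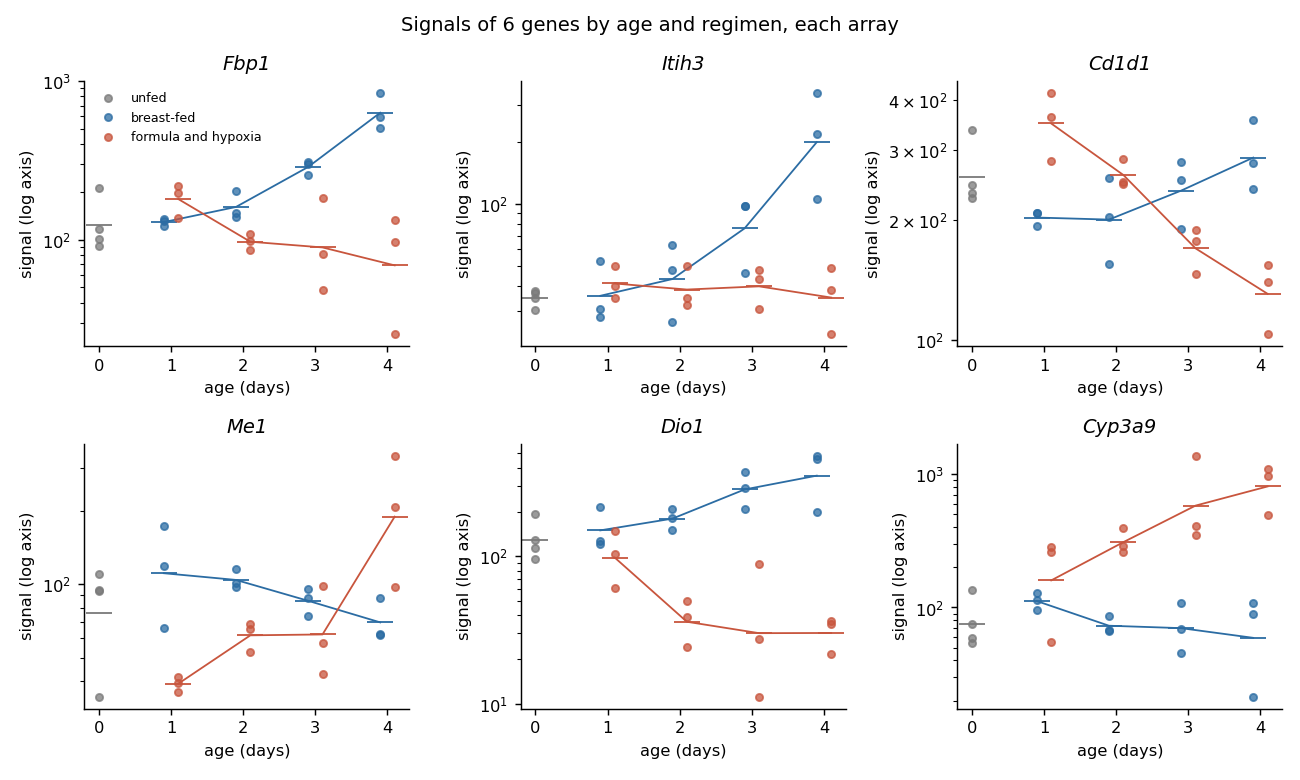
Quantile normalised signal (log axis) of Fbp1, Itih3, Cd1d1, Me1, Dio1 and Cyp3a9 against age in days, 1 point per array, in unfed, breast-fed and formula and hypoxia pups, with geometric means as marks joined by lines. The mean signal of Fbp1 went from 129 on day 1 to 646 on day 4 in breast-fed pups and from 184 to 85.1 under formula and hypoxia.

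By camera, the effect on several lists shifted upward from day 1 to day 4. These were fat tissue markers (1 of 11 higher, 2 over the list alone, median 0.74, adjusted p = 5.56e-05) and immediate early genes (0 of 23, 2 higher and 1 lower over the list alone, median 0.62, adjusted p = 0.00383). The called member of the fat tissue list was the enzyme gene Me1, and the amount of fat tissue in the samples was not measured. Smooth muscle markers (0 of 16, 1 over the list alone, median 0.48, adjusted p = 0.00301) also shifted upward, from a median effect of -0.40 on day 1. So did inflammatory genes (0 of 23, median 0.13, adjusted p = 0.0427). The effect on liver secreted proteins shifted downward (1 of 12 lower, 1 over the list alone, median -0.60, adjusted p = 0.00471). With an estimated correlation the adjusted p was 0.00241 for fat tissue, 0.0289 for liver proteins, 0.159 for immediate early genes and smooth muscle, and 0.287 for inflammatory genes. Without single arrays the count of 5 genes became 1 (breast-fed day 1 replicate 1, breast-fed day 4 replicate 2), 2 (formula and hypoxia day 1 replicate 1 or day 4 replicate 3, breast-fed day 4 replicate 1), 3 (formula and hypoxia day 1 replicate 2) or 8 (formula and hypoxia day 1 replicate 3). Fbp1 was called in each of these, and the calls of Itih3 (highest adjusted p = 0.179), Me1 (0.172), Bex3 (0.136) and Cd1d1 (0.0875) were lost in some. Limma called 0 genes in the F test (236 at an unadjusted p under 0.05 with all arrays) when single arrays were left out. Exceptions were breast-fed day 1 replicates 2 and 3 and day 4 replicate 3 (1 gene each), formula and hypoxia day 3 replicate 3 (5 genes) and day 4 replicate 3 (3 genes). The interaction could not be fitted within an accession run, since run 1 held no breast-fed array of day 4 and run 2 no formula and hypoxia array of day 1.

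The comparisons with unfed newborns asked what changed over the first day of life under each regimen. Under formula and hypoxia, Lcn2, a bacteriostatic siderophore-binding protein, was 5.27-fold higher on day 1 (2.76 to 10.1, n = 3 against 4 arrays), with a mean signal of 568 ± 306 (SD) against 100 ± 62.2. Scd2, a fatty acid desaturase gene, was 5.99-fold lower (3.25 to 11), Serpinh1 3.89-fold (2.63 to 5.75) and Cbx5 3.8-fold (2.47 to 5.84). The signal of Cbx5 on day 1 was 5.34, below the pseudocount, and its log2 change went from -2.64 to -1.01 between pseudocounts of 2 and 32. Ivns1abp and Pde6d were 2.75-fold (1.75 to 4.31) and 2.73-fold (1.70 to 4.39) lower, and Capn3, Cpt1a, Cgref1 and Cd59b were 2.38-, 2.36-, 2.35- and 2.28-fold higher. In all, 13 genes passed, 7 higher and 6 lower, with adjusted p-values of the named genes from 0.000578 to 0.0497, and the arrays of both groups did not overlap in any of the 10. Heat shock genes (1 of 21 lower, 1 over the list alone; median -0.38), proliferation genes (0 of 25, median -0.22) and fat tissue markers (1 of 11 lower, 1 over the list alone; median -0.36) were lower, each with adjusted p = 0.0417, and adjusted p = 0.744, 0.209 and 0.202 with an estimated correlation. Without formula and hypoxia replicate 1, 2 or 3 the count was 8, 7 or 5, without unfed replicate 3 or 4 it was 3 or 4, and within run 1, with a single unfed array, limma called 0 genes (318 at an unadjusted p under 0.05 with all arrays). All 3 formula and hypoxia arrays of day 1 lie in accession run 1 and 3 of the 4 unfed arrays in run 2, so the comparison nearly coincides with the run, and with the run as a term 4 genes passed. Scd2, Serpinh1 and Cbx5 were called without each single array, and the others lost their call in some (highest adjusted p = 0.398, for Pde6d).

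Under breast feeding, limma called 0 genes on day 1 against unfed newborns (n = 3 against 4), and 186 had an unadjusted p under 0.05. Brush border genes were higher as a list (0 of 16, 3 over the list alone; median 0.69, adjusted p = 1.89e-05), as were smooth muscle markers (0 of 16, median 0.62, adjusted p = 0.00024), and cholesterol synthesis genes were lower (0 of 16, 1 over the list alone; median -0.34, adjusted p = 0.000264). With an estimated correlation the adjusted p was 0.350, 0.235 and 0.350. The count was 1 without breast-fed replicate 3 or unfed replicate 4 and 3 without unfed replicate 2, and 3 within run 1. The direct comparison of both regimens on day 1 is the test of their difference, and it called the 9 genes given for that day.

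From day 1 to day 4, breast-fed pups showed higher Itih3 (4.72-fold, 2.87 to 7.76, n = 3 against 3 arrays), Fbp1 (4.67-fold, 2.58 to 8.44), Fabp5, a fatty acid binding protein gene (3.56-fold, 2.30 to 5.50), Atp2a2, a calcium pump gene (3.46-fold, 2.02 to 5.93), and Trim8 (3.06-fold, 1.96 to 4.77). These were among 10 genes called, all higher, with adjusted p-values from 0.00324 to 0.0296 and no overlap between the arrays of both days. Cholesterol synthesis genes (0 of 16, 3 over the list alone; median -0.56, adjusted p = 0.00148) and oxidative phosphorylation genes (0 of 30, median -0.43, mean -0.76, adjusted p = 0.00316) were lower as lists, with adjusted p = 0.353 for both with an estimated correlation. The lists of this comparison were not tested without day 4 replicate 2, which had lost 48 of 757 abundant probe sets. The count was 2 without breast-fed day 1 replicate 3 or day 4 replicate 1, 3 without day 1 replicate 2 or day 4 replicate 2, and 32 without day 4 replicate 3. Itih3 was called in each of these, and Fbp1, Fabp5, Trim8 and Atp2a2 reached adjusted p = 0.0737, 0.0646, 0.150 and 0.234. With the deposited scaling, in which day 4 replicate 1 was bright, 149 genes passed (147 higher), within run 2, with a single day 1 array, limma called 0 (541 at an unadjusted p under 0.05 with all arrays), and with the run as a term 2 were called.

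Under formula and hypoxia 427 genes passed from day 1 to day 4, 211 higher and 216 lower, and 310 of them changed more than 2-fold. Itgb4, the beta 4 integrin gene, was 8.95-fold higher (3.73 to 21.5, n = 3 against 3), Jun 8.35-fold (3.54 to 19.7), Map3k12 6.84-fold (3.11 to 15), Muc2 6.12-fold (3.02 to 12.4) and Ly6al 9.64-fold (3.31 to 28.1). Anapc15, a subunit gene of the anaphase-promoting complex, was 10.5-fold lower (4.18 to 26.3), the glucose transporter gene Slc2a2 5.83-fold (2.32 to 14.6), Mxd4 4.91-fold (2.66 to 9.06), Sem1 4.75-fold (2.76 to 8.16) and the mitochondrial ribosomal gene mrpl11 4.43-fold (2.78 to 7.07). Adjusted p-values ran from 0.000768 to 0.0115, with no overlap between the arrays of both days in the 10 genes. The signal of Anapc15 on day 4 was 7.01, below the pseudocount, and its log2 change went from -4.10 to -2.21 between pseudocounts of 2 and 32. Jun had 3.49 and 2.24 with these, and Map3k12 had 1.99 with 32. Smooth muscle markers (5 of 16, 5 over the list alone; median 0.74, adjusted p = 0.0189), immediate early genes (5 of 23; 5 higher and 1 lower over the list alone; median 0.43, adjusted p = 0.0225), fat tissue markers (3 of 11, 4 over the list alone; median 0.41, adjusted p = 0.0225) and enteroendocrine markers (2 of 13, 3 over the list alone; median 0.60, adjusted p = 0.0386) were higher. Red cell markers were lower (2 of 9, 5 over the list alone; median -0.62, adjusted p = 0.0225). With an estimated correlation the adjusted p was 0.212 for immediate early genes and 0.149 for the other 4 lists. Without formula and hypoxia day 4 replicate 1 the count was 150, Slc2a2 had adjusted p = 0.124 and Ly6al 0.0507, without day 1 replicate 1 the count was 275, and without day 1 replicate 3 Slc2a2 had 0.0613. Within run 1 the count was 397. The interaction test of the difference between both regimens called the 5 genes given for it.

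A last comparison asked whether genes that changed with age under breast feeding were shifted by formula and hypoxia. Across the 3185 genes, the mean of the day 2 and day 3 effects had a correlation of -0.047 (Pearson) or -0.049 (Spearman) with the breast-fed change from day 1 to day 4 (exact permutation p = 0.805, 400 arrangements, two-sided), and genes are not independent replicates.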

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

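All tests of explanations and all counts of splits given here were chosen only after the results they bear on were seen, whereas the interaction and F tests were planned.

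Genes and lists stood out when the effect of formula and hypoxia on day 4 differed from that on day 1 by a test of the difference itself. The log2 difference was -3.48 for Fbp1, -2.42 for Itih3, -1.85 for Cd1d1, -1.47 for Bex3 and 2.69 for Me1. On the F test over the 4 days, Fbp1, Cd1d1 and Mmp10 each had adjusted p = 0.0470, with daily effects of 0.46, -0.68, -1.58 and -3.02 for Fbp1, 0.76, 0.36, -0.46 and -1.09 for Cd1d1, and -1.58, -2.68, -0.25 and -0.75 for Mmp10. Among lists, the median difference was 0.74 for fat tissue markers, 0.62 for immediate early genes, 0.48 for smooth muscle markers, 0.13 for inflammatory cytokines and NF-kB targets, and -0.60 for liver secreted proteins. By exact permutation of list means over 400 arrangements, fat tissue (1.00) and liver proteins (-0.76) each had p = 0.005, the smallest possible, which adjusts to 0.08 over 32 lists, so the arrangements were too few for this pair of lists to pass. Of 15 values tested for an outlying unfed array, none had one.

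Chance was excluded as the source of the 364 genes of the mean over days, since 1 of 100 splits of the arrays within days (the real one) gave as many and the highest other gave 18. It was not excluded for the 7 called lists (6 of 100 splits as large, highest other 8) or for the 5 genes of the change from day 1 to day 4 (6 of 100, highest other 62). For the 13 genes of formula and hypoxia day 1 against unfed newborns, 1 of 35 splits (the real one) gave as many, the smallest share possible. The highest other split gave 12, so chance was not firmly excluded there. These splits took no account of the accession run, which nearly coincides with those groups, and with the run as a term 4 genes passed. For the 3 genes of the F test, 4 of 100 splits gave as many (highest other 61). For breast-fed day 1 against unfed newborns, limma called 0 genes (186 at an unadjusted p under 0.05), all 35 splits gave as many and the highest other gave 22. For the change and the F test, a split that exchanges the labels on some days only carries the regimen difference into the contrast. Counts of 62 and 61 can arise in this way, so these splits do not decide on chance for either test. The 22 genes from the highest split of breast-fed day 1 and unfed arrays may point to a structure of the samples. Its source was not tested. With 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real count and the highest other were 9 and 1 on day 1, 47 and 1 on day 2, 64 and 2 on day 3, 63 and 0 on day 4, 10 and 1 for breast-fed day 4 against day 1, and 427 and 0 for the same days under formula and hypoxia (1 of 10 splits as large in each).

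The fall of mast cell transcripts was weighed first. The mean difference of the fixed list of 8 genes was -0.71 within accession run 1 (exact permutation p = 0.002) and -0.73 without both arrays that had lost probe sets (p = 0.0001), which argues against the run and those arrays as the whole cause, although camera, which sets the list against other genes, gave adjusted p = 0.303 within run 1. A smaller share of connective tissue and muscle in the samples would lower the 48 fixed fibroblast and smooth muscle genes as far. Their mean fell by 0.22 on the log2 scale and that of the 8 mast cell genes by 0.74 (difference -0.52, exact permutation p = 0.00136). Medians per array, taken over signals and not over changes, also differed by -0.52 (exact permutation p = 0.00331). Mcpt4 (-3.08) and Mcpt1 (-2.36) carry most of the mean, and their fall can change which genes set the median signal. Neither score therefore decides whether the list as a whole fell further than the connective tissue and muscle genes. The median effect of the 8 genes was -0.24, and 4 of them were not called. Fewer mast cells or less protease transcript per cell may lie behind the fall, and with tryptase genes not lower and cross-hybridisation of related chymases not tested, neither was settled.

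For the rise of immediate early genes, the mean difference was 0.45 within run 1 (exact permutation p = 0.001), 0.47 without both arrays (p = 2.5e-05, the smallest possible) and 0.54 after the beta-actin ratio was regressed out (p = 5e-05). These values argue against the run, the lost probe sets and RNA integrity as read by that ratio as the whole cause. A response of the tissue to the regimen is a candidate explanation, and so is a longer or rougher handling of these pups before the tissue was frozen, which the labels do not describe and no test covered.

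More genes passed from day 1 to day 4 under formula and hypoxia (427) than under breast feeding (10). The fit shares 1 estimate of the spread over all groups, so both comparisons had the same median standard error (0.32). Equal precision was thus assumed and not tested, so unequal precision stays open. Breast-fed day 4 replicate 2 had lost 48 of 757 abundant probe sets. With array weights both counts rose, and in a fit of only the groups compared the breast-fed count fell, as given further on. The slope of the breast-fed changes on the others, corrected for measurement error, was 0.599. It ran from 0.509 to 0.729 when each of the 12 arrays was left out. A slope below 1 also arises where changes are equally large but differ between genes, so it does not settle their size. Across genes the SD of the changes was 0.55 under breast feeding and 0.69 under formula and hypoxia. Within run 1 limma called 397 genes under formula and hypoxia, which argues against the run as the source of that count. The breast-fed comparison lies across the runs, so a smaller breast-fed change may still carry a run effect, and a biological difference in pace stays open as well.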

How the results depend on the processing

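The alternatives without both arrays that had lost probe sets and with the beta-actin ratio as a term, and the tests on replicate numbers, were chosen only after the data were seen. Called named genes kept direction and call in 1996 of 2323 values under other settings, 320 missed the threshold with the same direction, and with 1 array left out 2260 of 2478 kept them. Named genes that were not called passed in 88 of 5547 values. Called lists kept their call in 81 of 91 values under other settings and in 152 of 168 with 1 array left out. The fits within an accession run are not among these list values. Within run 1 the mast cell and antioxidant lists lost their call (camera adjusted p = 0.303 and 0.248). The 7 reversals were all within run 2 on day 4, P4ha1 0.0113, Acsl5 0.0237, Cd74 0.0764, Hbb-b1 -0.0350, Alas2 -0.133, Hbb -0.0577 and Hbg1 -0.123, where a single formula array was assumed to vary like the other groups.

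Counts that moved by more than 1.5 times are given against those of the mean over days (364), days 1 to 4 (9, 47, 64, 63), the change from day 1 to day 4 (5), the F test (3), breast-fed day 1 against unfed (0), formula and hypoxia day 1 against unfed (13), and day 4 against day 1 under breast feeding (10) and under formula and hypoxia (427). With the deposited scaling they were 5 on day 1, 22 on day 2, 9 for the change, 0 for the F test, 6 against unfed under formula and hypoxia and 149 for breast-fed day 4. With a common median they were 21 on day 2, 39 on day 4, 3 for the change, and 1 and 4 against unfed. The F test called 0 genes with a pseudocount of 2 and without a trend, and 1 with a pseudocount of 32. The 60th percentile filter gave 1 for breast-fed day 1 against unfed. With 1 test per probe set the mean over days gave 549, the F test 1 and breast-fed day 4 gave 19. Fitting only the groups compared gave 4, 83, 4 and 11 on days 1 to 4, 0 for the change and the F test, 2 against unfed under formula and hypoxia and 2 for breast-fed day 4. Array weights gave 593, 58 on day 1, 148 on day 2, 122 on day 4, 20 for the change, 17 for the F test, 62 and 92 against unfed, and 112 and 720 for day 4 against day 1.

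With the accession run as a term the counts were 203 for the mean, 0 on day 1, 19 on day 4, 0 for the F test, 1 and 4 against unfed and 2 for breast-fed day 4. Within run 1 they were 163 for the mean, 30 on day 3, 0 for the F test, and 3 and 0 against unfed, and within run 2 limma called 0 for the mean, day 4 and breast-fed day 4. Without both arrays they were 31 on day 3, 38 on day 4, 1 for the change, 1 for the F test, 8 against unfed under formula and hypoxia and 3 for breast-fed day 4. The beta-actin term gave 2 for the change, 0 for the F test, 1 and 5 against unfed and 21 for breast-fed day 4. Camera with an estimated correlation called 2 lists in place of 7. Beside these counts of 0 from limma, the unadjusted p was under 0.05 with all arrays for 852 genes of the mean, 291 on day 1, 478 on day 4, 225 for the change, 236 for the F test, 318 against unfed under formula and hypoxia and 541 for breast-fed day 4. Fewer arrays entered within the runs and without both arrays. For all these counts the cause was not tested.

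With each array left out, counts ran from 291 to 398 for the mean, 0 to 3, 19 to 28, 29 to 83 and 16 to 56 on days 1 to 4, 1 to 8 for the change, 0 to 5 for the F test, 0 to 3 and 3 to 18 against unfed, 2 to 32 and 150 to 360 for day 4 against day 1, and 4 to 9 for lists. The correlation with the breast-fed change by age ran from -0.119 to 0.0449. No sign of pairing by replicate number was seen, as 0 of 3 pairs with the same number had a residual correlation over 0.1 in each of the 8 comparisons (from -0.473 to 0.0858). With so few pairs, pairing was not excluded. The replicate block gave 5 on day 1, 29 on day 2, 0 for the F test, and 1 and 5 against unfed, and moved no other count by more than 1.5 times.

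With the deposited scaling the median change of all genes moved by more than 0.1 in several comparisons. It became 0.17 on day 1, 0.14 on day 3 and -0.24 for the change from day 1 to day 4. For day 4 against day 1 it became 0.32 under breast feeding and 0.11 under formula and hypoxia. With a common median it was -0.14 on day 3. The split of 149 higher and 215 lower became 90 and 245 with a common median. With the deposited scaling the split on day 1 went from 2 and 7 to 3 and 2, on day 2 from 22 and 25 to 8 and 14, on day 3 from 31 and 33 to 35 and 23 (19 and 42 with a common median), on day 4 from 22 and 41 to 12 and 42, and for the change from 1 and 4 to 0 and 9 (0 and 3). For formula and hypoxia day 1 against unfed it went from 7 and 6 to 1 and 3 with a common median, and for day 4 against day 1 from 211 and 216 to 123 and 211 (182 and 126 with the deposited scaling). Of 303 values of named genes, 0 changed sign with the scaling. Day 4, the change and breast-fed day 4 could not be fitted within run 1, nor days 1 to 3, the change, the F test and the comparisons under formula and hypoxia across days within run 2. Signal limits folds near the floor, as the filter lay at a signal of 24.0 and Mcpt4 under formula and hypoxia averaged 7.22.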

Other observations

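The permutation tests of list means, the comparison of the daily effects with each other and the test of late against early days were all chosen only after the data were seen, though what the last would show was written down first.

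By exact permutation of the list means within days (160000 arrangements), 13 of 32 lists differed between the regimens, 9 higher and 4 lower. Beside the 7 called lists these were exocrine pancreas markers (0.23, adjusted p = 0.0190, higher in 10 of 12 formula and hypoxia arrays), bile acid handling (0.29, 0.0190, 11 of 12), inflammatory genes (0.21, 0.0190, 10 of 12), antimicrobial proteins (0.25, 0.0195, 11 of 12), glucocorticoid and ion transport genes (0.13, 0.0462, 10 of 12) and junction genes (0.37, 0.0478, 10 of 12). Immediate early genes had adjusted p = 0.0004 (unadjusted p = 1.25e-05, the smallest possible) and mast cell markers 0.0006. The number of lists was 6 within accession run 1 and 10 without both arrays that had lost probe sets. Heat shock and endoplasmic reticulum stress genes, at -0.12 with all arrays (0.573), had -0.38 within run 1 (0.008) and -0.33 without both arrays (0.0004).

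Most genes that passed from day 1 to day 4 under formula and hypoxia had the same sign under breast feeding. Of 211 that rose, 191 were higher there, and of 216 that fell, 189 were lower (89.0% together). Of the 10 genes called under breast feeding, 7 were called under both regimens. The correlation of the changes across genes was 0.52, with no array shared.

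The daily effects of formula and hypoxia were more alike within days 1 and 2 (r = 0.49 across genes, exact permutation p = 0.01, the smallest possible with 400 arrangements) and within days 3 and 4 (r = 0.55, p = 0.01) than between days 1 and 3 (0.24, p = 0.09), 1 and 4 (0.27, p = 0.07), 2 and 3 (0.31, p = 0.02) or 2 and 4 (0.31, p = 0.01). Each p sets a single correlation against permuted labels, and the differences between the correlations were not tested. A breast-fed array with lost probe sets lies on day 3 and another on day 4. The correlations were not computed without them, so these arrays stay open as a source of the value for days 3 and 4. A candidate explanation is an effect that changes between the early and the late days. The late minus early effect called 16 genes, 5 higher and 11 lower late. Of 100 splits within days, 2 gave as many, the real one included, and the highest other gave 53. The contrast was picked from the same daily effects. Splits that exchange labels on some days only also carry the regimen difference into it, so these splits do not decide on chance. Chosen after their values were seen, Fos went from 0.06 early to 2.01 late (adjusted p = 0.0380), Pck1 from -2.21 to 1.67 (0.0395) and Cd1d1 from 0.56 to -0.78 (0.0152). Late values are means of days 3 and 4. Pck1 had 3.33 on day 3 alone, so its late mean does not show a rise on both days. Without breast-fed day 3 replicate 3, Pck1 was not called on day 3 (limma adjusted p = 0.249). Without breast-fed day 4 replicate 2, the day 4 change of Fos was smaller, at 1.25, and was not called. The count was 8 without both arrays that had lost probe sets and 4 with the accession run as a term, and a run effect stays open because every breast-fed day 4 array lies in run 2.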
